A study of Homo sapiens with 27 samples.

How the data were processed

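RNA was sequenced from cultures of MCF10DCIS.com, a human breast line of the MCF10A family used as a model of ductal carcinoma in situ. Per the labels' protocols, flasks were seeded with 500000 cells, left for 6 h and given calcium oxalate crystals at 0.1 mg/mL. RNA was extracted from thawed samples, polyadenylated RNA was enriched with magnetic beads and libraries were made with an NEBNext UltraExpress kit. The time between adding the crystals and collecting the cells is not given in the sources used here. The 27 libraries fall into 6 groups by their titles and treatment labels: 7 untreated controls, and 4 libraries for each of 5 crystal forms. The forms are calcium oxalate monohydrate plates (COM) and calcium oxalate dihydrate (COD) as dumbbells (DB), spheres (SPH), thick bipyramids (TK) and thin bipyramids (TN). Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be partly technical.

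The authors deposited 1 table per library with expected counts per gene, effective lengths and derived units, per the file headers. Only the expected counts and the lengths were used. The submitters' processing notes name Trim Galore, RSEM, Bowtie2 and the genome build GRCh38. Versions, parameters, the annotation release and the strand setting are not given in the sources used here. RSEM assigns a read that fits several genes in fractions, so genes with near-identical copies (HSPA1A and HSPA1B, SPRR2A and SPRR2D, EIF3CL, CBSL, pseudogenes) are reported as uncertain. Without a stated strand setting, overlapping antisense genes cannot be told apart. The expected counts were rounded to whole numbers. The tables hold 60683 genes as Ensembl identifiers with symbols. Coordinates are those of GENCODE 29 on GRCh38, to which 15988 of the 16173 genes tested (98.9%) were matched by identifier, of which 13298 are protein coding.

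Total counts per library ran from 13115649 to 38672448 with a median of 19251210, and 20886 to 25735 genes had at least 1 count. No 2 libraries of a group agreed within sampling noise, at a chi-square per degree of freedom of 2.387 to 63.34 per pair. Each was counted as 1 sample, though this does not show separate cultures. Pairs of TK (at most 7.717) and of controls C, E and F (at most 5.308) were closest, against at least 9.878 in each other form.

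Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 6 groups, libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted over all 27 libraries. Each contrast was tested with the quasi-likelihood F-test, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no fold threshold. Each crystal form was compared with the controls, each pair of forms was compared at the same dose, both bipyramids were compared with both other COD forms, and a joint test asked for a difference between any of the 6 groups. Fold changes are log2 with the standard error (SE) of the fit. Levels are CPM, counts scaled to the TMM-adjusted library size, with the SD over the libraries of a group. Levels of the liver transcripts in single libraries, SPP1 aside, are scaled to the plain library total instead.

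Before the data were examined, 37 gene lists were fixed, covering stress, inflammatory, growth, differentiation, adhesion, matrix and metabolic programmes, signs of RNA quality and markers of other cell types. The 34 lists with at least 5 measured members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists and the 5 control comparisons. The same test was run with the correlation estimated from the data, beside fry, which asks whether the members move one way on balance. Members were also counted with p-values adjusted over the list alone. Genes named in the text follow a rule fixed with the lists. For each control comparison these are the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM and every crystal library on the same side of the control mean, and up to 2 called members from each of the 9 lists with the smallest camera p. For each contrast of forms they are the 3 largest rises and falls. SPP1, MMP1, CDH1, VIM, KRT5, MKI67, HMOX1 and IL1B were followed in every comparison. Of the genes that the rule selects, 3 are not reported here. The same rule was applied to the fit with a library set term described next.

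The serial numbers in the deposited names divide the libraries into runs of 10, 12 and 5 that hold different replicate letters of each group, called here library sets 1, 2 and 3. They were recognised after the data had been seen, from a first principal component that separated them. Set 1 (serial numbers 1 to 10) holds controls A and B and the A and B libraries of COM, DB, SPH and TN. Set 2 (11 to 22) holds controls C to F, the C libraries of those forms and all 4 TK libraries. Set 3 (23 to 27) holds control G and their D libraries. The library at the boundary, TN C (serial number 11), is like set 1 in fragment length (297 nt) and in read-through transcripts (6.04 CPM, where the others of set 2 have at least 31.4), and the set term was also fitted with it in set 1. Every contrast was therefore also fitted with the library set as a term, and within each set by a model with a mean per group and set. There a group with 1 library in a set is assumed to vary like the others, as in all of set 3 and for COM, DB, SPH and TN in set 2. A planned batch term at serial numbers 1 to 14 against 15 to 27 divides set 2 and is reported with the alternatives. Shared controls were handled by simulating 100 draws of unchanged groups, by the overlap that independent lists would give, and by splitting the controls between the comparisons (A to C against D to G).

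Alternatives were DESeq2 1.42.0 (as a test, and its size factors with the edgeR test), limma voom with quality weights, no low-count filter, a filter of at least 1 CPM in at least 4 libraries, only the groups compared in the fit, the replicate letter as a block, 2 surrogate variables (sva 3.50.0), effective lengths as offsets, a 2-fold threshold, other control subsets, and leaving out each library in turn. Counts were also refitted on other splits of the libraries, at most 100 per comparison.

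The steps were tested on simulated counts drawn from the means and library sizes of the real genes, with 66 or 67 genes changed at each of 3 fold sizes among 16173. Without library sets in the simulation, 73.1% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 98.5% of those changed 4-fold were recovered for COM against control. The shares were 80.6%, 89.6% and 100% for DB, 71.6%, 91% and 98.5% for SPH, 77.6%, 95.5% and 98.5% for TK, and 76.1%, 91% and 97% for TN. With the effects of the library sets simulated, the pooled fit recovered 67.2%, 77.6% and 98.5% for COM, 64.2%, 86.6% and 98.5% for DB, 67.2%, 86.6% and 95.5% for SPH, 61.2%, 83.6% and 100% for TK, and 58.2%, 89.6% and 98.5% for TN. The fit with the set term then recovered 68.7% to 79.1%, 86.6% to 95.5% and 98.5% to 100% over the 5 forms. No changed gene was called in the wrong direction. TPM and FPKM in the files, which are scaled within each library, were not used here.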

Results

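Messenger RNA was counted in MCF10DCIS.com cells that had received 1 of 5 forms of calcium oxalate crystal at 0.1 mg/mL, and in untreated controls. COM crystals are plates of the monohydrate. DB, SPH, TK and TN crystals are the dihydrate grown as dumbbells, spheres, thick bipyramids and thin bipyramids. Each form was measured in 4 libraries and the controls in 7, and 16173 genes were tested. A joint edgeR test called 3468 genes as different between any of the 6 groups, and 3759 with the library set in the model. Against controls, 543 genes were called for COM, 915 for DB, 7 for SPH, 2569 for TK and 695 for TN. Inflammatory NF-kB targets were the one list called higher for every form, though with estimated correlation not for TK (adjusted p = 0.089). Heat shock genes were called lower for every form but TK, and with estimated correlation only for COM and DB (adjusted p = 0.053 for SPH and 0.15 for TN).

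The libraries also differed by library set. The first principal component held 22.3% of the variance, the second 11.5% and the third 6.44%, and the first placed all 12 libraries of set 2 above 0 and all 15 others below 0. The untreated controls of set 2 differed from those of set 1 in 2253 genes, of which 1046 were higher and 1207 lower. MMP1 was lower in the set 2 controls by log2 2.05 (SE 0.22), MMP10 by 2.50 (SE 0.20) and FOSB by 2.14 (SE 0.34). CHAC1 was higher by 2.51 (SE 0.22). The single control of set 3, assumed to vary like the other groups, differed from the set 1 controls in 6 genes and from the set 2 controls in 876. TN C, the set 2 library with the lowest serial number, has a mean fragment length of 297 nt, where the others of set 2 reach at most 243.2 nt and set 1 starts at 257.9 nt. Its place in set 2, and with it every TN value within set 2, is therefore uncertain. All 4 TK libraries belong to set 2, so against controls TK can be compared free of set only with those of set 2. Values with the set as a term in the model (the set term) and within sets therefore stand beside many pooled ones.

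**Figure D1:**
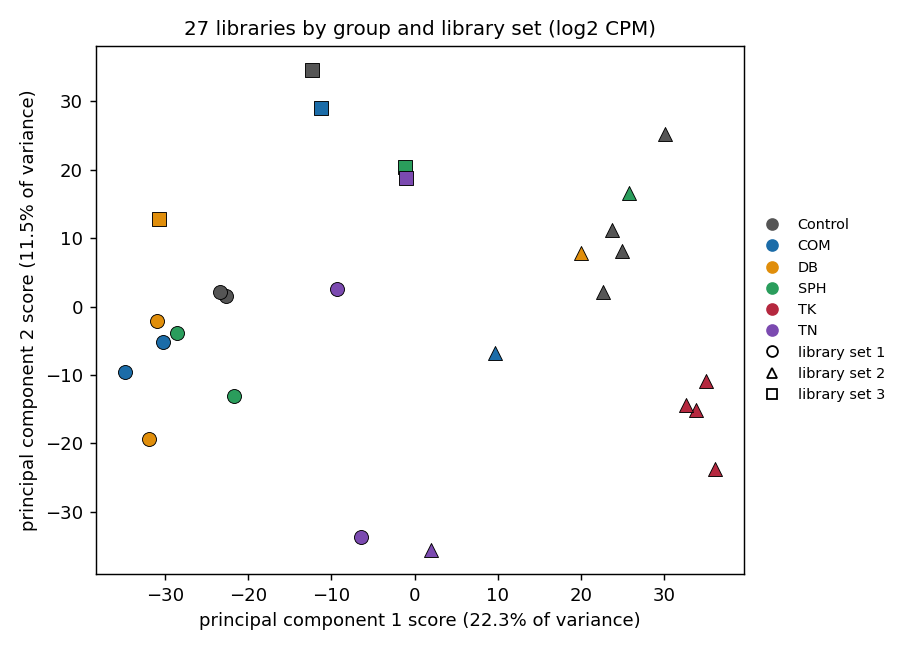
Principal components of log2 CPM over the genes tested, with each point 1 library coloured by crystal form and shaped by library set; the axes are the first component (22.3% of variance) and the second (11.5%). All 12 libraries of set 2 lie to the right of 0 and the 15 libraries of sets 1 and 3 to the left.

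COM plates raised inflammatory genes and lowered heat shock genes (4 libraries against 7). PTGS2, which encodes the prostaglandin-forming enzyme cyclooxygenase-2 (protein coding, chromosome 1, 186671791 to 186680427), rose by log2 1.69 (SE 0.16, adjusted p = 5.4e-07), from 18.9 ± 3.85 CPM in the controls to 61.2 ± 16.1 CPM. The rise was 1.93 within set 1, 1.33 within set 2 and 1.92 within set 3. CCL20, a chemokine that attracts lymphocytes and dendritic cells (chromosome 2, 227805739 to 227817564), rose by 1.60 (SE 0.19), and CXCL8, which attracts neutrophils (chromosome 4, 73740506 to 73743716), rose by 1.25 (SE 0.16). IL1B, the cytokine interleukin-1 beta, rose by 1.47 (SE 0.30, adjusted p = 0.0068) and by 1.06 with the set term. Of 19 measured NF-kB targets and inflammatory cytokines, 15 rose, none fell and 4 were not called, and 18 rose when adjusted over the list alone. The camera adjusted p was 2.6e-47, and adjusted p = 5e-05 with estimated correlation.

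Among 18 heat shock proteins, the chaperones that refold damaged proteins, 10 fell with COM and none rose (12 adjusted over the list alone; camera adjusted p = 5e-17, and adjusted p = 0.003 with estimated correlation). HSPA1A, an inducible HSP70 chaperone (chromosome 6, 31815464 to 31817946), fell by log2 1.2 (SE 0.23, adjusted p = 0.004), from 91.6 ± 25.2 to 39.9 ± 11.8 CPM. Its near-identical neighbour HSPA1B fell by 1.02 (SE 0.19), and reads cannot be assigned surely between these copies. The co-chaperone DNAJA1 fell by 0.65 (SE 0.09) and HSPH1 by 0.54 (SE 0.09). CHORDC1, an HSP90 co-chaperone, fell by 0.81 (SE 0.16). Of 22 cell division genes 10 fell and none rose (19 adjusted over the list alone; camera adjusted p = 3e-20, but adjusted p = 0.088 with estimated correlation). KIF20A, a kinesin of cytokinesis, fell by 0.56 (SE 0.07, adjusted p = 3.9e-05) and the mitotic cyclin CCNB1 by 0.43 (SE 0.08). DNA replication and G1/S genes fell in 4 of 22 cases (12 adjusted over the list alone; camera adjusted p = 4.3e-08, but adjusted p = 0.3 with estimated correlation), among them UHRF1 by 0.45 (SE 0.10) and TYMS by 0.31 (SE 0.07). MKI67, the proliferation marker Ki-67, was at 256 ± 32.9 CPM against 348 ± 51.2 (log2 -0.44, SE 0.13, adjusted p = 0.067).

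Among the other genes called with COM, MMP9, a gelatinase (chromosome 20, 46008908 to 46016561), rose by log2 2.91 (SE 0.46, adjusted p = 0.00049) from 1.34 ± 0.818 to 10.4 ± 5.88 CPM. PLAU, the urokinase plasminogen activator (chromosome 10, 73909177 to 73917497), rose by 0.87 (SE 0.14). These were the 2 of 18 matrix protease genes that rose (9 adjusted over the list alone; camera adjusted p = 9.2e-07, but adjusted p = 0.3 with estimated correlation). PMEPA1, a TGF-beta target, rose by 0.99 (SE 0.25), with 3 of 18 members of that list called (camera adjusted p = 3.3e-06, but adjusted p = 0.16 with estimated correlation). The cornified envelope genes SPRR2A and SPRR2D, which are close paralogs and not surely separable, rose by 1.58 (SE 0.43) and 1.35 (SE 0.34). Of 23 keratinocyte differentiation genes 5 rose (camera adjusted p = 3.3e-06, but adjusted p = 0.3 with estimated correlation). HBEGF, a ligand of the EGF receptor, rose by 0.84 (SE 0.13), and 4 of 21 ERK targets rose (camera adjusted p = 6.5e-06, but adjusted p = 0.16 with estimated correlation). The p53 targets TNFRSF10B, a death receptor, and PLK3 rose by 0.27 (SE 0.06) and 0.38 (SE 0.09), with 3 of 22 members called (camera adjusted p = 7.1e-05, but adjusted p = 0.12 with estimated correlation). BANP, MYB and DNASE1 fell by 0.85 (SE 0.14), 0.78 (SE 0.14) and 0.85 (SE 0.12).

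SLC7A11, the cystine transporter (chromosome 4, 138164097 to 138242349), rose with COM by log2 1.08 (SE 0.18, adjusted p = 0.0011). CHAC1, a glutathione-degrading enzyme induced by ATF4 (chromosome 15, 40952962 to 40956519), rose by 1.36 (SE 0.37, adjusted p = 0.041), and by 3.24, 0.91 and 2.82 within sets 1, 2 and 3. Of 22 unfolded protein and ATF4 genes 3 rose and none fell in the pooled fit (camera adjusted p = 0.0081, but adjusted p = 0.44 with estimated correlation). With the set term 13 rose and 3 fell (camera adjusted p = 9.3e-10, and adjusted p = 0.024 with estimated correlation), among them DDIT3 by 1.34 (SE 0.18) and SESN2 by 1.13 (SE 0.15). The set term raised the number of genes called for COM from 543 (295 higher, 248 lower) to 1029 (638 higher, 391 lower), with 537 in both. Within sets 1, 2 and 3 the edgeR test called 661, 81 and 16 genes, and the pooled test called 131 without COM A, 127 without COM B, 826 without COM C, 306 without Control C and 286 without Control F.

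DB dumbbells raised genes of epithelial junctions as well as inflammatory genes, and lowered heat shock genes (4 libraries against 7). PTGS2 rose by log2 1.55 (SE 0.16, adjusted p = 1.7e-06), and by 1.55, 1.23 and 2.25 within sets 1, 2 and 3. LIF, a cytokine of the interleukin-6 family (chromosome 22, 30240447 to 30246851), rose by 0.77 (SE 0.10) from 423 ± 57.3 to 722 ± 81.2 CPM. Of the 19 NF-kB targets 10 rose and none fell (14 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.4e-15, and adjusted p = 0.014 with estimated correlation). DSG3, a desmosomal cadherin (chromosome 18, 31447795 to 31478702), rose by 0.83 (SE 0.09, adjusted p = 5.3e-06) from 162 ± 11.7 to 288 ± 32 CPM. The tight junction genes CLDN1 and OCLN rose by 0.53 (SE 0.10) and 0.62 (SE 0.12), and CDH1, the gene of E-cadherin, by 0.39 (SE 0.07). In all, 9 of 24 epithelial junction genes rose and none fell (17 adjusted over the list alone; camera adjusted p = 7.7e-12, and adjusted p = 0.015 with estimated correlation).

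EGR3, an immediate early transcription factor (chromosome 8, 22687659 to 22693302), rose with DB by log2 1.29 (SE 0.14, adjusted p = 2.2e-06), and by 1.23, 1.30 and 1.06 within the sets. ZNF750, a regulator of epidermal differentiation (chromosome 17, 82829435 to 82840578), rose by 1.21 (SE 0.15, adjusted p = 1.9e-05), and TMCC3 by 1.41 (SE 0.20). SPRR2A and SPRR2D, uncertain as paralogs, rose by 1.60 (SE 0.43) and 1.51 (SE 0.34), with 6 of 23 keratinocyte differentiation genes called higher (camera adjusted p = 2.3e-05, but adjusted p = 0.35 with estimated correlation). PLAU and its receptor PLAUR rose by 1.04 (SE 0.14) and 0.65 (SE 0.14), 2 of the 4 matrix protease genes that rose (camera adjusted p = 9.5e-06, but adjusted p = 0.36 with estimated correlation). IL1B rose by 1.15 (SE 0.30, adjusted p = 0.028). Of 21 cholesterol synthesis genes 3 rose (10 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.9e-06, but adjusted p = 0.3 with estimated correlation), including STARD4 by 0.54 (SE 0.12) and CYP51A1 by 0.38 (SE 0.11).

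Heat shock proteins fell with DB in 9 of 18 cases and none rose (13 adjusted over the list alone; camera adjusted p = 1.8e-11, and adjusted p = 0.015 with estimated correlation). HSPA1A fell by log2 1.16 (SE 0.23, adjusted p = 0.0049), DNAJA1 by 0.49 (SE 0.08) and AHSA1, an activator of HSP90, by 0.49 (SE 0.08). DNA replication and G1/S genes fell in 10 of 22 cases (15 adjusted over the list alone; camera adjusted p = 4.5e-11, but adjusted p = 0.24 with estimated correlation), among them GINS2 by 0.52 (SE 0.11) and the helicase subunit MCM5 by 0.38 (SE 0.08). Cell division genes fell in 5 of 22 cases (camera adjusted p = 7.6e-10, but adjusted p = 0.24 with estimated correlation), including KIF20A by 0.46 (SE 0.07) and UBE2C by 0.34 (SE 0.06). Oxidative phosphorylation genes fell in 5 of 23 cases (18 adjusted over the list alone; camera adjusted p = 8.6e-12, but adjusted p = 0.24 with estimated correlation), such as NDUFS5 by 0.59 (SE 0.16) and NDUFA2 by 0.50 (SE 0.14), subunits of complex I. Cytosolic ribosomal protein genes fell in 2 of 24 cases (12 adjusted over the list alone; camera adjusted p = 1.3e-07, but adjusted p = 0.39 with estimated correlation), namely RPL37 and RPLP2, each by 0.35 (SE 0.11). BCYRN1, a short non-coding RNA with related pseudogene copies, fell by 1.48 (SE 0.29), and SNHG19 and TPRG1 by 0.95 (SE 0.28) and 0.89 (SE 0.23). Over all libraries NDUFS5 and BCYRN1 were lowest in DB B (106 and 7.14 CPM), which had the longest fragments (319.1 nt). Both were highest in Control D (246 and 53.9 CPM), which had the shortest (197.6 nt), whereas RPL37 was highest in COM A (697 CPM, 268.5 nt). Whether fragment length accounts for part of these falls was not tested.

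CHAC1 rose with DB by log2 1.34 (SE 0.37) in the pooled fit and by 2.86, 0.88 and 3.47 within the sets, and SESN2 by 0.88 (SE 0.24). The unfolded protein and ATF4 list had 4 of 22 members higher and 2 lower (camera adjusted p = 0.042, but adjusted p = 0.53 with estimated correlation). Adding the set term gave 13 higher and 3 lower (camera adjusted p = 3.2e-07, but adjusted p = 0.054 with estimated correlation). Genes called for DB numbered 513 higher and 402 lower, and with the set term 957 higher and 663 lower, 902 of them in both. Within sets 1, 2 and 3 the test called 339, 85 and 368 genes. The pooled test called 214, 243, 1863 and 346 without DB A, B, C and D, and 1585, 497, 450, 545 and 439 without Controls B, C, D, E and F.

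SPH spheres changed few genes, all of them upward (4 libraries against 7). EGR3 rose by log2 1.01 (SE 0.14, adjusted p = 0.0011) from 11.7 ± 1.61 to 23.7 ± 4.12 CPM, and by 1.11, 1.01 and 0.43 within sets 1, 2 and 3. ZNF750 rose by 0.79 (SE 0.15, adjusted p = 0.038), OVOL1, an epithelial transcription factor, by 0.71 (SE 0.13), SEMA7A by 0.66 (SE 0.13), LIF by 0.57 (SE 0.10), DAPP1, a phosphoinositide-binding adaptor, by 0.48 (SE 0.09) and NET1, named after its value was seen, by 0.40 (SE 0.07). These are the 7 genes called in the pooled test, with 727 genes at an unadjusted p under 0.05. Leaving out 1 library left 3 without Control B, 2 without Control G, 4 without SPH D and 1 without any of the others. The fit with the set term called 18, 13 higher and 5 lower. The 5 were HSPA1B, at log2 -0.80 (SE 0.09, adjusted p = 1.5e-05), HSPA1A, at -0.82 (SE 0.12, adjusted p = 0.0011), KIF20A, at -0.31 (SE 0.06), TENT5A, at -0.53 (SE 0.10), and DNASE1, at -0.50 (SE 0.10). PTGS2 was at 28.9 ± 6.46 CPM, against 18.9 ± 3.85 in the controls.

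Gene lists were called with SPH with at most 1 member called in each. Of 34 lists 17 were called, 11 higher and 6 lower, of which 1 was called with estimated correlation. This was the NF-kB list, with 1 of 19 members called (5 adjusted over the list alone; median log2 0.24; camera adjusted p = 9.6e-11, and adjusted p = 0.046 with estimated correlation, or 0.053 with the set term). Heat shock proteins had a median of -0.16 with no member called (camera adjusted p = 5.8e-08, but adjusted p = 0.053 with estimated correlation, or 0.019 with the set term). Cell division genes had a median of -0.18 with none called (camera adjusted p = 6.5e-13, but adjusted p = 0.19 with estimated correlation). Cholesterol synthesis (median 0.15; camera adjusted p = 1.7e-08, but adjusted p = 0.24 with estimated correlation) and YAP/TAZ targets (median 0.07; camera adjusted p = 0.00048, but adjusted p = 0.15 with estimated correlation) were higher, with no member called. Oxidative phosphorylation genes were lower (median -0.17; camera adjusted p = 2.9e-06, but adjusted p = 0.39 with estimated correlation). Mitochondrially encoded transcripts, counted as a sign of RNA quality, were lower for SPH with the set term (median -0.16; camera adjusted p = 0.00031, but adjusted p = 0.48 with estimated correlation) and had a pooled median of 0.03 (adjusted p = 0.8).

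TK thick bipyramids lowered the matrix protease genes MMP1 and MMP10 (4 libraries against 7, all 4 in set 2). MMP1, the interstitial collagenase (chromosome 11, 102789920 to 102798160), fell by log2 3.42 (SE 0.63, adjusted p = 0.00086), by 2.39 with the set term and by 2.20 within set 2, and its level was 3.59 ± 0.953 CPM against 38.1 ± 27.1. MMP10, the adjacent stromelysin-2 gene (chromosome 11, 102770503 to 102780628), fell by 4.02 (SE 0.85, adjusted p = 0.0024), by 2.62 with the set term and by 2.39 within set 2. The gelatinase MMP2 fell by 1.06 (SE 0.19), or by 0.68 within set 2, and TIMP1, an inhibitor of these enzymes, by 1.42 (SE 0.25). Of 18 matrix protease genes 10 fell and 1 rose (camera adjusted p = 3.8e-05, but 0.4 with estimated correlation). With the set term 8 fell and 3 rose (0.00034, but 0.28), and 13 were already lower in set 2 controls than in those of set 1. The mesenchymal and matrix list fell in 7 of 19 members and rose in none (8 adjusted over the list alone; camera adjusted p = 0.00023, but adjusted p = 0.051 with estimated correlation). In it FN1, the gene of fibronectin, fell by 0.91 (SE 0.21), SPARC by 0.25 (SE 0.09) and VIM, the gene of vimentin, by 0.41 (SE 0.11, adjusted p = 0.012). Integrins ITGB3 and ITGB5 fell by 0.90 (SE 0.15) and 0.63 (SE 0.09), among 4 of 26 adhesion genes that fell (camera adjusted p = 0.00021, but adjusted p = 0.28 with estimated correlation).

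DNA replication genes rose together with TK. Of 22 genes 18 rose and none fell (21 adjusted over the list alone, 17 with the set term; camera adjusted p = 9.4e-17, but 0.13 with estimated correlation). RRM2, a subunit of ribonucleotide reductase (chromosome 2, 10120698 to 10131419), rose by log2 0.63 (SE 0.09, adjusted p = 0.00019) from 183 ± 12.8 to 283 ± 10.5 CPM. The G1/S cyclins CCNE1 and CCNE2 rose by 0.71 (SE 0.12) and 0.86 (SE 0.20). Cell division genes KIF11 and TPX2 rose by 0.32 (SE 0.10) and 0.30 (SE 0.09), the 2 of 22 called (camera adjusted p = 0.00019, but adjusted p = 0.46 with estimated correlation). MKI67 was at 440 ± 33.4 CPM against 348 ± 51.2 (log2 0.34, SE 0.13, adjusted p = 0.079).

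PTGS2 rose with TK by log2 1.41 (SE 0.16, adjusted p = 9.6e-06), and by 1.30 within set 2. TNFAIP3, a feedback inhibitor of NF-kB, rose by 0.75 (SE 0.10) and CCL2, a monocyte chemokine, by 1.36 (SE 0.19). Of 19 NF-kB targets 10 rose and none fell (11 adjusted over the list alone; camera adjusted p = 2.9e-08, but adjusted p = 0.089 with estimated correlation). SLC7A11 rose by 1.09 (SE 0.18), CHAC1 by 1.5 (SE 0.37) and STC2 by 1.15 (SE 0.32), where the values within set 2 were 0.87, 0.85 and 0.64. KLF4, a transcription factor of epithelial differentiation (chromosome 9, 107484852 to 107490482), rose by 1.21 (SE 0.17), and IGFL1 by 1.13 (SE 0.23). In contrast, FOS and FOSB, AP-1 subunits of the immediate early class, fell by 2.16 (SE 0.35, adjusted p = 0.00033) and 3 (SE 0.61), or by 1.54 and 1.63 within set 2. Of 21 immediate early genes 10 fell and 2 rose (13 and 2 adjusted over the list alone, 7 and 2 with the set term; camera adjusted p = 0.00046, but 0.31 with estimated correlation). CAMK2B, a calcium/calmodulin-dependent kinase (chromosome 7, 44217150 to 44334577), fell by 1.56 (SE 0.23, adjusted p = 0.00017), by 1.77 with the set term and by 1.72 within set 2. PTPRH and DHRS9 fell by 2.15 (SE 0.52) and 1.93 (SE 0.55), or by 1.43 and 0.56 within set 2.

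Hypoxia and glycolysis genes fell with TK in 9 of 23 cases (camera adjusted p = 0.00077, but adjusted p = 0.24 with estimated correlation), including the aldolase ALDOC by log2 0.74 (SE 0.14) and the collagen prolyl hydroxylase P4HA1 by 0.52 (SE 0.09). Cholesterol synthesis genes rose in 3 of 21 cases (camera adjusted p = 0.0014, but adjusted p = 0.47 with estimated correlation), among them LSS, the enzyme that forms lanosterol, by 0.85 (SE 0.12). Heat shock proteins went both ways, with 3 higher and 3 lower (camera adjusted p = 0.48). Mitochondrially encoded transcripts were lower with TK in the pooled test (camera adjusted p = 0.023, but adjusted p = 0.63 with estimated correlation) and had a median log2 of -0.01 with the set term (adjusted p = 0.7). Of the 2569 genes called, 1282 were higher and 1287 lower. No other form had as many in the pooled test or with the set term, but DB had more with voom (4697 against 4009) and with controls C to G alone (1884 against 1437), and TN within set 1 had 2301 against 2028 for TK within set 2. Without TK A the pooled test called 1655 and without TK C 1472. The set term called 2487, of which 2043 were in both, and the comparison within set 2, of 4 TK libraries with 4 controls, called 2028. LCN2, the antimicrobial protein lipocalin-2, was at log2 -0.70 (SE 0.54, adjusted p = 0.4) in the pooled fit and rose by 0.62 (SE 0.10, adjusted p = 0.00019) with the set term.

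**Figure D2:**
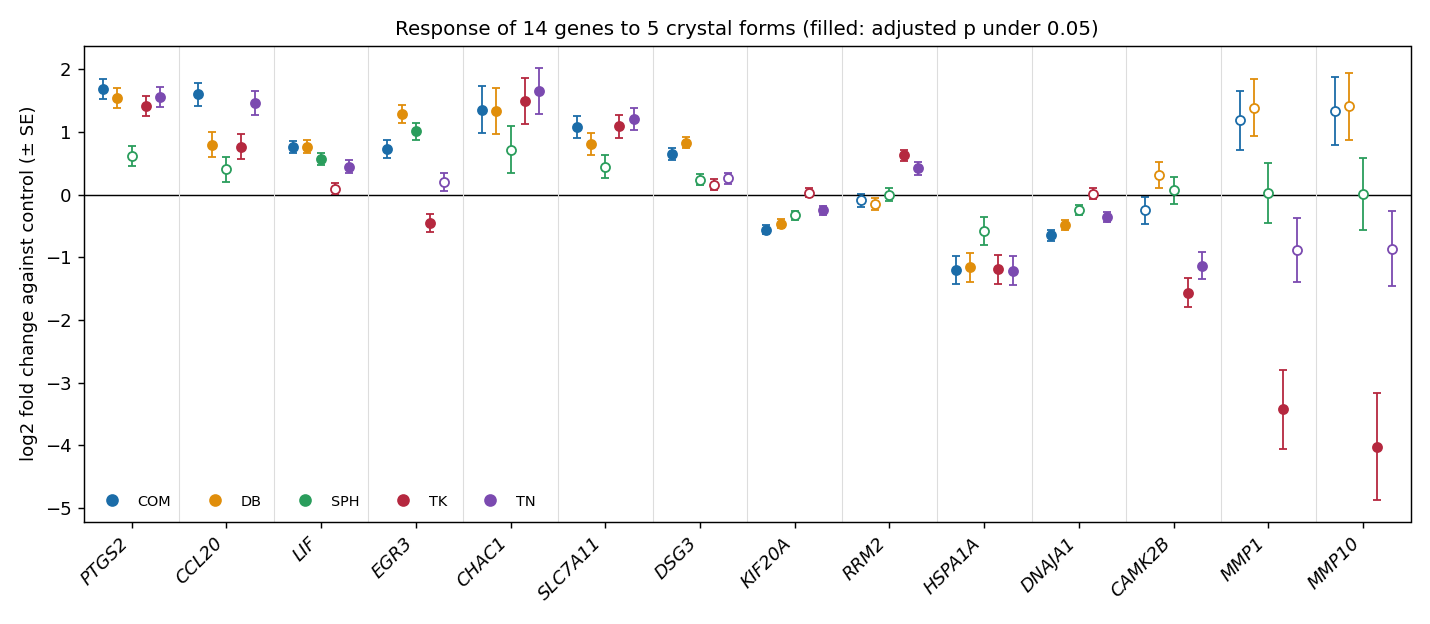
Log2 fold change against controls of 14 named genes for each crystal form from the pooled edgeR fit, with bars for the SE and filled points for an adjusted p under 0.05. PTGS2 lies between 1.41 and 1.69 for COM, DB, TK and TN, and MMP10 reaches -4.02 with TK.

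TN thin bipyramids raised chemokines and amino acid stress genes and lowered HSPA1A and CAMK2B (4 libraries against 7). PTGS2 rose by log2 1.56 (SE 0.16, adjusted p = 2.9e-06) and by 1.66, 1.61 and 1.62 within sets 1, 2 and 3. CCL20 rose by 1.47 (SE 0.19) and CXCL1, a neutrophil chemokine (chromosome 4, 73869393 to 73871242), by 1.04 (SE 0.13). Of 19 NF-kB targets 14 rose and none fell (18 adjusted over the list alone; camera adjusted p = 3.7e-32, and adjusted p = 0.00038 with estimated correlation). SLC7A11 rose by 1.21 (SE 0.18, adjusted p = 0.00068), SESN2 by 1 (SE 0.24) and CHAC1 by 1.66 (SE 0.37), the last by 3.58, 1.22 and 2.98 within the sets. The unfolded protein and ATF4 list had 4 of 22 members higher (camera adjusted p = 0.0011, but adjusted p = 0.33 with estimated correlation), and 11 with the set term (camera adjusted p = 2.7e-10, and adjusted p = 0.022 with estimated correlation). In the same fit 5 of 17 glutathione and one-carbon genes also rose (camera adjusted p = 0.015, but adjusted p = 0.32 with estimated correlation), among them PSPH by 0.67 (SE 0.09) and MTHFD2 by 0.55 (SE 0.07).

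HSPA1A fell with TN by log2 1.21 (SE 0.23, adjusted p = 0.0036) and HSPA1B by 0.90 (SE 0.19), and 4 of 18 heat shock proteins fell in all (camera adjusted p = 2.3e-05, but adjusted p = 0.15 with estimated correlation). CAMK2B fell by 1.13 (SE 0.22), and by 1.28, 0.75 and 0.85 within the sets. FGFR1, a receptor of fibroblast growth factors (chromosome 8, 38400215 to 38468834), fell by 1.24 (SE 0.26, adjusted p = 0.0069), CAPN6 by 1.11 (SE 0.19), the non-coding RNA H19 by 1.15 (SE 0.20) and NES, the gene of nestin, by 1.32 (SE 0.38). Hypoxia and glycolysis genes fell in 7 of 23 cases and rose in 1 (11 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.00019, but adjusted p = 0.19 with estimated correlation), including P4HA1 by 0.45 (SE 0.09) and CA12 by 0.40 (SE 0.10). Lysosome and autophagy genes rose in 5 of 24 cases (camera adjusted p = 0.00039, but adjusted p = 0.27 with estimated correlation), among them SQSTM1, an autophagy receptor, by 0.39 (SE 0.08) and the proton pump subunit ATP6V0D1 by 0.42 (SE 0.08). DNA replication genes rose in 3 of 22 cases (camera adjusted p = 0.00019, but adjusted p = 0.46 with estimated correlation), including CCNE1 by 0.65 (SE 0.12) and CCNE2 by 0.90 (SE 0.20). The tight junction gene CLDN1 rose by 0.58 (SE 0.10) and KLF4 by 1.03 (SE 0.17).

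Mitochondrially encoded transcripts were higher with TN (median log2 0.36; camera adjusted p = 0.0012, but 0.52 with estimated correlation) and COM (median 0.30; 0.0036, but 0.57). With the set term the adjusted p was 0.047 for TN and 0.1 for COM. SPP1, the gene of osteopontin (chromosome 4, 87975650 to 87983426), rose with TN by 3.49 (SE 0.70, adjusted p = 0.0053), but its values within the sets were 4.14, -0.64 and 0.70. Its level was 18.2 CPM in TN B and at most 1.06 CPM in the other TN libraries. TN B also held 1730 CPM of 20 liver transcripts, against at most 8.75 CPM in the other TN libraries. Genes called for TN numbered 400 higher and 295 lower, and with the set term 1107 higher and 789 lower, with 694 in both. Within sets 1, 2 and 3 the test called 2301, 817 and 16 genes, and with TN B left out the set term called 1904. The pooled test called 133 without TN A, 276 without TN B and 1220 without TN D.

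MMP1 was called in the pooled fit for none of the 4 forms spread over all sets. It was at log2 1.19 (SE 0.47, adjusted p = 0.17) with COM, 1.39 (SE 0.46, adjusted p = 0.073) with DB, 0.03 (SE 0.48, adjusted p = 1) with SPH and -0.88 (SE 0.51, adjusted p = 0.34) with TN. With the set term it rose by 1.06 (SE 0.26, adjusted p = 0.011) for DB and fell by 1.04 (SE 0.28, adjusted p = 0.016) for TN. The TN values within sets 1, 2 and 3 were -2.05, 0.01 and -0.83. MMP10 fell with TN by 1.09 (SE 0.28) with the set term, at -1.96, 0.10 and -0.90 within the sets. HMOX1, the oxidative stress enzyme heme oxygenase-1, was called for no form, at 2.66 to 3.78 CPM against 2.98 ± 0.547. KRT5, a basal keratin, was called for no form either, with log2 values from -0.27 (SE 0.12) for COM to 0.12 (SE 0.11) for TK.

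**Figure D3:**
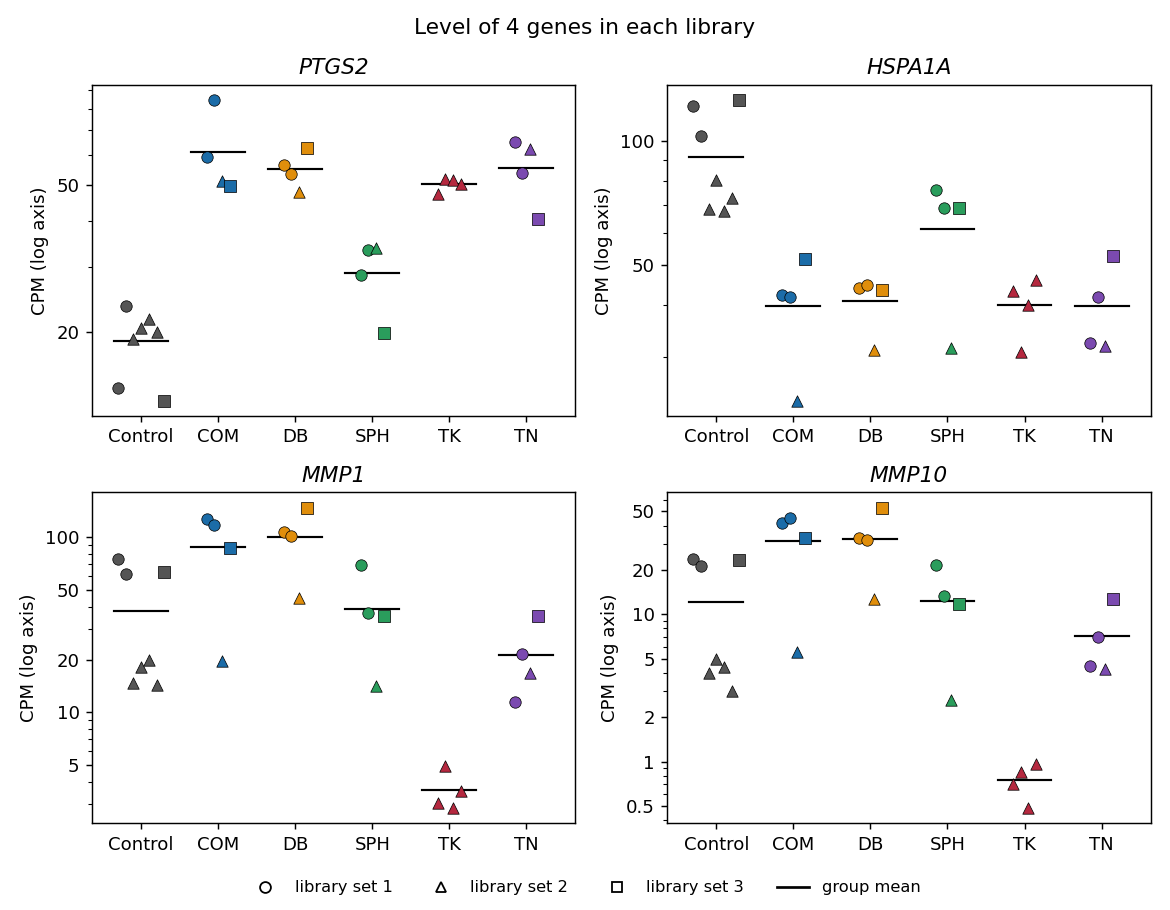
Level in CPM on a log axis of PTGS2, HSPA1A, MMP1 and MMP10 in each of the 27 libraries, by group, with the marker for the library set and a bar for the group mean. MMP1 is at 2.83 to 4.94 CPM in the 4 TK libraries and at 14.3 to 75.2 CPM in the 7 controls.

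Integrin and adhesion genes were called higher for COM (1 of 26 members; camera adjusted p = 0.00077, but 0.33 with estimated correlation), DB (4 members; 0.00014, but 0.27) and SPH (no member; 0.024, but 0.49). With the set term SPH was not called (adjusted p = 0.28). TGF-beta targets were called higher for DB (3 of 18; camera adjusted p = 0.00077, but 0.3 with estimated correlation) and SPH (none; 0.00019, but 0.25) and lower for TK (4; 0.0077, but 0.41, and 0.044 with the set term). ERK targets were called higher for DB (6 of 21; camera adjusted p = 0.00023, but 0.24 with estimated correlation) and SPH (none; 3e-04, but 0.24) and lower for TK (5; 0.035, but 0.46). Immediate early genes were called higher for COM (4 rose and 1 fell; camera adjusted p = 0.013, but 0.46 with estimated correlation), DB (4 rose; 0.0042, but 0.41) and SPH (1 rose; 0.018, but 0.47). With the set term only DB was called (adjusted p = 0.035, against 0.1 for COM and 0.25 for SPH). p53 targets were called higher for DB (3 of 22; camera adjusted p = 0.0024, but 0.24 with estimated correlation), SPH (none; 7.1e-05, but 0.12) and TN (2; 0.00084, but 0.2). Basal markers were higher for COM (1 of 17; camera adjusted p = 0.035, but 0.3 with estimated correlation) and lower for TK (7; 0.023, but 0.27, and 0.018 with the set term).

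Hypoxia genes were called lower for COM (4 of 23; camera adjusted p = 0.0065, but 0.3 with estimated correlation), DB (2 fell and 1 rose; 0.02, but 0.39) and SPH (none; 0.048, but 0.45). Epithelial junctions were called higher for COM (2 of 24; camera adjusted p = 0.00045, but 0.24 with estimated correlation) and SPH (none; 0.00082, but 0.24). Fatty acid synthesis genes were higher for DB (1 of 12; camera adjusted p = 0.02, but 0.45 with estimated correlation) and SPH (none; 0.0021, but 0.33). Oxidative phosphorylation genes were lower for COM (none of 23; camera adjusted p = 0.0036, but 0.59 with estimated correlation) and TN (none; 0.02, but 0.64). With the set term TN was not called (adjusted p = 0.11). Inflammasome genes were lower for TK (3 of 12 fell and 1 rose; camera adjusted p = 0.0014, but 0.13 with estimated correlation). Unfolded protein and ATF4 genes were higher for TK (4 of 22; camera adjusted p = 0.012), but not with the set term (0.11) or estimated correlation (0.45). Matrix proteases (camera adjusted p = 0.02, but 0.62 with estimated correlation) were higher for SPH, and ribosomal proteins (0.014, but 0.66) and NRF2 targets (0.029, but 0.46) were lower, with no member called. With the set term SPH was not called for matrix proteases (median log2 -0.02, adjusted p = 0.64) or ribosomal proteins (0.059). Lysosome genes were higher for COM (3 of 24; camera adjusted p = 0.013, but 0.058 with the set term and 0.44 with estimated correlation) and calcium and oxalate transport genes for DB (1 of 19; 0.016, but 0.24 with the latter).

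Some lists were called for no form in the pooled fit. The smallest camera adjusted p was 0.082 for interferon-stimulated genes (TN), 0.062 for luminal markers (DB), 0.12 for mineralization and bone matrix (TK), 0.075 for apoptosis and necroptosis (COM), 0.18 for endocytosis (TN), 0.16 for glutathione and one-carbon metabolism (DB), 0.091 for nuclear-retained RNA (TK) and 0.25 for leukocyte markers (COM). Metallothioneins, fibroblast markers and endothelial markers had 3, 4 and 2 measured members, too few to test. With the set term the apoptosis list was called for COM (camera adjusted p = 0.044, but adjusted p = 0.16 with estimated correlation), as was the glutathione list for TN.

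DB and COM differed in few genes at the same dose (4 libraries each). The pooled test called 5. ENC1 was higher with DB by log2 0.39 (SE 0.07, adjusted p = 0.05, under the threshold before rounding), and TNFAIP2, a TNF-induced gene, was lower by 0.57 (SE 0.10, adjusted p = 0.013). The other 3 lie below the level that the naming rule asks for: CCL2 was lower by 1.53 (SE 0.23), SMAD6 was lower by 1.12 (SE 0.19) and SLC15A2 was higher by 1.09 (SE 0.20). The count was 1 without COM B or DB A, 2 without COM A or DB B, 3 without DB D and 9 without DB C. Within the sets 16, 4 and 37 were called. Adding the set term gave 32, including CCL20, lower with DB by 0.76 (SE 0.16, adjusted p = 0.047), and FGFR1, higher by 0.70 (SE 0.13, adjusted p = 0.015). A p that misses the threshold does not show that both forms act alike: for MMP1 the difference was 0.19 with an SE of 0.53. Gene lists were compared between forms after the results against controls had been seen. NF-kB targets were lower with DB (1 of 19 called, 3 with the set term; camera adjusted p = 3.9e-12, but adjusted p = 0.077 with estimated correlation). Epithelial junctions were higher with no member called (camera adjusted p = 3.4e-06, but adjusted p = 0.13 with estimated correlation).

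SPH gave weaker inflammatory expression than COM. PTGS2 was lower by log2 1.07 (SE 0.18, adjusted p = 0.017), and by 1.21, 0.60 and 1.32 within sets 1, 2 and 3. CCL20 was lower by 1.19 (SE 0.22, adjusted p = 0.026), and by 1.44, 0.67 and 0.98 within the sets. Of 19 NF-kB targets 6 were lower and none higher, and 11 were lower with the set term (camera adjusted p = 1.1e-36, and adjusted p = 4e-04 with estimated correlation). CYP1B1, a cytochrome P450, was lower by 0.66 (SE 0.13, adjusted p = 0.045). With the set term 5 of 18 heat shock proteins were higher with SPH (camera adjusted p = 5.9e-12, but adjusted p = 0.074 with estimated correlation), among them HSPA1A by 0.62 (SE 0.13, adjusted p = 0.024), and IL1B was lower by 0.72 (SE 0.15, adjusted p = 0.02). In all 12 genes were called, all lower with SPH, 88 with the set term and 137, 0 and 4 within the sets. The pooled count was 4 without COM A, 1 without COM B or SPH B and 2 without SPH A or SPH D.

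SPH against DB gave no called gene in the pooled edgeR test, with 1023 genes at an unadjusted p under 0.05, where DESeq2 called 12 and voom 48. The smallest values belonged to ACYP1, at log2 0.78 (SE 0.14, adjusted p = 0.055), DSG3, at -0.59 (SE 0.11, adjusted p = 0.055), and DAPP1, at -0.50 (SE 0.10, adjusted p = 0.093), named after their values were seen. The set term gave 40 called genes, 6 higher and 34 lower, and 3, 7 and 513 were called within sets 1, 2 and 3. In that fit DSG3 was lower with SPH by 0.59 (SE 0.10, adjusted p = 0.0054), MMP10 by 1.47 (SE 0.29, adjusted p = 0.02) and MMP1 by 1.39 (SE 0.30, adjusted p = 0.038). Epithelial junctions were lower (2 of 24 members with the set term; pooled camera adjusted p = 1.8e-10, but adjusted p = 0.077 with estimated correlation). DNA replication genes were higher with no member called (camera adjusted p = 8.9e-15, but adjusted p = 0.16 with estimated correlation).

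TK had lower MMP1 and MMP10 than every non-bipyramid form, in the pooled fit and with the set term. Against COM, CLSPN, a replication checkpoint adaptor (chromosome 1, 35720218 to 35769967), was higher by log2 1.21 (SE 0.14, adjusted p = 6.1e-06) and by 1.25 within set 2. Against DB its difference was 1.21 (SE 0.14), and 0.98 within set 2. In the pooled fit 20 of 22 DNA replication genes (6 were higher in controls of set 2 than of set 1) were higher than with COM (camera adjusted p = 1.2e-23, but 0.1 with estimated correlation), 21 than with DB (8.2e-26, but 0.1) and 19 than with SPH (1.6e-17, but 0.13). MKI67 was higher than with COM, DB and SPH by 0.78, 0.62 and 0.54 (SE 0.15 each). MMP10 was lower by 5.36 (SE 0.88), 5.43 (SE 0.87) and 4.03 (SE 0.89), at 2.86, 4.04 and 1.78 within set 2. MMP1 was lower by 4.61 (SE 0.68), 4.81 (SE 0.68) and 3.45 (SE 0.67), at 2.45, 3.65 and 1.98 within set 2. PTPRH, a receptor tyrosine phosphatase, was lower than with COM by 3.03 (SE 0.55) and ABCC2, an efflux transporter, higher by 1.74 (SE 0.40), or by 1.05 and 0.88 within set 2.

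Heat shock proteins were higher with TK than with COM in 10 of 18 cases (camera adjusted p = 9.6e-09, but 0.1 with estimated correlation) and than with DB in 11 (1.4e-06, but 0.13). NF-kB targets were lower than with COM in 11 of 19 cases (camera adjusted p = 0.00013, but adjusted p = 0.23 with estimated correlation). IL1B was lower by log2 1.95 (SE 0.36, adjusted p = 5e-04) and by 0.67 within set 2. CAMK2B was lower than with DB by 1.88 (SE 0.25) and than with SPH by 1.63 (SE 0.25), at 2.15 and 2.10 within set 2. Genes called numbered 3674 against COM, 4263 against DB and 2034 against SPH, which became 2349, 2881 and 906 with the set term. The pooled count against COM was 2415 without COM A, and that against SPH 843 without SPH A, 1215 without TK A and 1071 without TK C. Within set 2 each of these comparisons sets 4 TK libraries against a single library, and 730, 577 and 644 genes were called.

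TN had higher CLSPN than COM, by log2 0.79 (SE 0.14, adjusted p = 0.015), and by 1.05, 0.41 and 0.55 within the sets. Of 22 DNA replication genes 6 were higher than with COM (camera adjusted p = 1.6e-23, but 0.1 with estimated correlation) and 15 than with DB (5e-24, but 0.1). CAMK2B was lower than with DB by 1.45 (SE 0.24, adjusted p = 0.003), by 1.77, 1.18 and 1.26 within the sets. TRPV3, a heat-gated calcium channel, was lower than with DB by 1.58 (SE 0.25, adjusted p = 0.0019). CDH1 was lower than with DB by 0.47 (SE 0.08), and 4 of 24 epithelial junction genes were lower (camera adjusted p = 5.4e-07, but adjusted p = 0.13 with estimated correlation). SPP1 was higher than with DB by 3.01 (SE 0.82, adjusted p = 0.039), again from TN B alone. Against COM 109 genes were called, and 814 with the set term, but 2084, 1 and 2 within sets 1, 2 and 3. Against DB 543 were called, and 1671 with the set term, but 2630, 14 and 199 within the sets. Leaving out 1 library moved the pooled count to 1 (without COM A) to 461 (without TN D) against COM and to 89 (without TN A) to 942 (without DB C) against DB.

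PTGS2 was higher with TN than with SPH by log2 0.94 (SE 0.18, adjusted p = 0.036), at 0.94, 0.88 and 1.03 within the sets, and CXCL1 by 0.92 (SE 0.15, adjusted p = 0.014). Neither was called in a fit on the SPH and TN libraries alone, and 3 of 35 splits, the real one included, had as many calls. Of 19 NF-kB targets 3 were higher (camera adjusted p = 9.8e-18, and adjusted p = 0.026 with estimated correlation, or 0.053 with the set term). EGR3 was lower by 0.82 (SE 0.16, adjusted p = 0.036), and DRAM1, a p53-induced regulator of autophagy, was higher by 0.48 (SE 0.09). The test called 11 genes, from 2 (without SPH C or TN A) to 134 (without TN D) when 1 library was left out, 206 with the set term and 991, 81 and 0 within the sets. Mitochondrially encoded transcripts were also higher with TN (camera adjusted p = 0.00037, but adjusted p = 0.52 with estimated correlation).

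The 2 bipyramids differed from each other in 41 genes, of which 10 were also called with the set term (35 genes). Within set 2, where TN C alone meets the TK libraries, 873 were called. The pooled count was 0 without TK B or TK D and 188 without TN C, 4 with a term for the serial number, 444 in DESeq2 and 834 with the replicate letter as a block. SYNM, an intermediate filament gene, was lower with TN by log2 0.80 (SE 0.14, adjusted p = 0.024), by 0.96 with the set term and by 0.89 within set 2. HSPH1 was lower by 0.50 (SE 0.10, adjusted p = 0.039), one of 4 heat shock proteins lower with TN (camera adjusted p = 4.3e-07, but 0.13 with estimated correlation). APOBEC3G, a cytidine deaminase, and SERPINA1, a protease inhibitor, were higher by 1.94 (SE 0.43) and 1.61 (SE 0.32), and by 1.47 and 0.65 within set 2. TN B, with its liver transcripts, had 272 CPM of SERPINA1, against 79.6 to 142 in other TN libraries. The difference for MMP1 was 2.54 (SE 0.66, adjusted p = 0.074), and 1.35 (SE 0.41, adjusted p = 0.2) with the set term, so a similar fall in both was not shown.

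Both bipyramids together were compared with both other dihydrate forms (8 libraries each). CAMK2B was lower by log2 1.54 (SE 0.18, adjusted p = 4.7e-06), by 1.74 with the set term and by 1.64 within set 2. IGFL1, an insulin growth factor-like gene, was higher by 1.26 (SE 0.19) and CLSPN by 0.84 (SE 0.10), the latter by 0.51 within set 2. Of 22 DNA replication genes 21 were higher (camera adjusted p = 7.2e-25, but 0.1 with estimated correlation), and 19 of 22 cell division genes (4.5e-12, but 0.2). MMP1 and MMP10 were lower by 2.86 (SE 0.44) and 3.15 (SE 0.55), or by 1.71 and 1.67 within set 2, and 12 of 18 matrix protease genes were lower (camera adjusted p = 1.7e-07, but adjusted p = 0.28 with estimated correlation). Integrin and adhesion genes were lower in 11 of 26 cases (4.5e-07, but 0.16 with estimated correlation), immediate early genes in 13 of 21 with 2 higher (4.6e-06, but 0.21). CDH1 and VIM were both lower, by 0.37 (SE 0.06) and 0.30 (SE 0.09). The test called 3422 genes, 1737 higher and 1685 lower, 3201 with the set term and 540 within set 2, where 5 bipyramid libraries meet 2 others.

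Genes called against the controls overlapped between forms. COM and DB shared 276 genes in the same direction and none in opposite directions, where independent lists would share 15.5 (n1×n2/N summed over both directions). COM and TN shared 164, against 11.8, DB and TN 152 with 1 opposite, against 20, and TK and TN 400, against 55.2. TK shared 93 genes with COM and 46 in opposite directions (43.1 independent), and 96 with DB and 82 opposite (72.7). All comparisons use the same 7 controls, which by itself correlates their fold changes. In 100 simulated draws of unchanged groups, with shared controls and set effects, the mean was 0 shared calls. This does not bear on the overlap, as unchanged groups give few calls. The covariance of fold changes was 0.0149 for COM and DB, against 0.0701 in the data, and -0.0146 for TK and TN, against 0.0684. With the controls split, each form having its own, 50 genes were shared for COM and DB (3.6 independent), 34 for COM and TN (1.02), 17 for DB and TN (0.916) and 130 for TK and TN (23.5). The covariance over all genes then fell to 0.0155 for COM and DB (r = 0.09) and to -0.000622 for TK and TN (r = -0.002). The split followed replicate letters and so also divides the library sets. DAPP1 was the only gene raised by all 5 forms. The fit with the set term added EIF5, IFRD1, SLC25A25 and TUFT1, and in it HSPA1A, HSPA1B and TENT5A were lowered by all 5. COM, DB, TK and TN raised 30 genes in common and lowered 6, or 108 and 21 with the set term.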

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

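Of the tests of explanations given here, that on the level of the set 2 controls was written before its result was seen, and the others were chosen after. Samples far from the rest of their group were found in 11 of 114 groups tested, and chance flags about 1 in 20 groups.

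TN B held 1730 CPM of 20 liver transcripts, against 3.53 to 8.75 CPM in the other TN libraries, with ALB (albumin) at 653 CPM, AFP at 237 and APOB at 120. Its SPP1 level of 18.2 CPM stood apart from 0.228 to 1.06 CPM. The same liver transcripts stood apart in Control D, at 44.9 CPM against 3.13 to 12.9, and in DB C, at 32.6 CPM against 3.8 to 5.87. SPH C held as much, 36.21 CPM, against 3.394 to 14.78, without standing apart in the same test. A response to thin bipyramids is argued against, since the highest other TN library, at 8.75 CPM, lies below the highest control, at 44.9. RNA of liver cells in the library could account for the pattern: over the 20 transcripts, which are not independent replicates, the rank order in TN B followed that of the traces summed over the other 26 libraries (Spearman rho 0.85). How such RNA would have entered, and whether TN B itself was the source of the traces elsewhere, stays open.

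MMP1 and MMP10 responded differently by form. With the set term, the edgeR test of the difference gave MMP1 a log2 of -3.45 for TK against DB and -2.10 for TN against DB. For MMP10 it gave -3.47 for TK against COM, -1.94 for TN against COM, -3.66 for TK against DB and -2.13 for TN against DB. The library set alone is argued against, because both genes fell with TK within set 2, the weaker by -2.20. A culture or processing day shared by the 4 TK libraries cannot be told apart from the form, as 0 TK libraries lie outside set 2. The bipyramid form may account for part of the fall: with the set term TN lowered both genes, the weaker by -1.04, though in the single TN library of set 2 they were at 0.01 and 0.10. With TN B also left out MMP1 was at -0.9 (adjusted p = 0.059, over all alternatives 9.3e-05 to 0.81) and MMP10 at -0.96 (adjusted p = 0.044, over all alternatives 7.3e-05 to 0.95). Voom without the set term gave -0.25 and 0.09. TN C is like set 1 in fragment length. On the first component it lies at 2, just on the side of set 2, whose other libraries lie at 9.7 (COM C) or above. TN D of set 3 lies at -1. With it in set 1 the fall with TN was -1.65 for MMP1 and -1.71 for MMP10. Which property of the crystals matters was not tested.

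The unfolded protein and ATF4 response was smaller in set 2. Over the 22 genes, the mean response to COM, DB, SPH and TN was higher in set 1 than in set 2 by a median log2 of 0.22 (camera p = 4.1e-08, and p = 0.0042 with estimated correlation). CHAC1 rose by 3 (SE 0.21) in set 1 and by 0.88 (SE 0.14) in set 2, a difference of 2.13 (SE 0.25, adjusted p = 0.00089), 1 of 10 genes whose response differed. Of 8 members looked at, STC2 also differed, by 1.04 (SE 0.13, adjusted p = 0.0023), and the other 6 missed the threshold, from ATF3 at -0.09 (adjusted p = 0.94) to TRIB3 at 0.6 (adjusted p = 0.062). The controls of set 2 were higher than those of set 1 by a median of 0.53 over the 13 members called for any of the 4 forms, which may account for the smaller rise. Both tests use the same control libraries and so are not independent. Whether the controls of set 2 were stressed in culture or in handling stays open, and no biological explanation was tested.

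TN D had 13.7 M counts (13707174 in full) against 35.1 to 38.7 M in the other TN libraries. VIM was at 1170 CPM in Control A against 836 to 963 in the other controls. KRT5 was at 2730 CPM in COM C against 2030 to 2100, and at 2970 CPM in DB C against 1990 to 2080. HSPA1A was at 31.2 CPM in DB C against 43.7 to 44.8, and at 31.5 CPM in SPH C against 68.8 to 76.1. COM C, DB C and SPH C are the libraries of these forms that belong to set 2. MKI67 was at 206 CPM in SPH A against 331 to 336.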

How the results depend on the processing

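The fits with the library set as a term, with the first set extended to serial number 11, with TN B left out or with protein-coding genes only were chosen after seeing the data, and the other alternatives before. DESeq2 size factors, a filter of 1 CPM in 4 libraries and every other alternative not given here, apart from those that leave out 1 library, left a count within 1.5 times of the reported one. Of 9167 values of named genes under the alternatives, 7934 kept their side of the threshold, 770 lost the threshold, 460 gained it and 3 changed direction with a call in either fit. Of the 7934, 146 changed sign without a call in either fit. The cause of the changes was not tested, except that fewer libraries and a fold threshold leave fewer calls by construction. The lowest depth, 13115649 counts, limits genes of a few CPM.

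LCN2 with TK, at log2 -0.70 in the pooled fit, was the only gene to change direction with a call in either fit, to 0.62 with the library set term, 0.61 with it over protein-coding genes and 1.13 with 2 surrogate variables.

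With the library set as a term the genes called were 1029 for COM, 1620 for DB, 18 for SPH and 1896 for TN against controls. Between forms they were 32 for DB against COM, 88 for SPH against COM, 2349 for TK against COM, 814 for TN against COM, 40 for SPH against DB, 1671 for TN against DB, 906 for TK against SPH and 206 for TN against SPH. In the same order, with TK against DB added after TN against COM and SPH against DB, the first set extended to serial number 11 gave 994, 1519, 20 and 2093 against controls, then 27, 91, 2010, 1649, 46, 2340, 2802, 626 and 561, and 78 for TN against TK. Protein-coding genes with the set term gave 1065, 1763, 20 and 1930 against controls, and 37, 116, 2443, 1013, 59, 1959, 1021 and 297 between forms in the first order. With TN B left out the set term gave 1904 for TN, 458 for TN against COM, 986 against DB, 137 against SPH and 16 against TK.

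With 2 surrogate variables 1150 genes were called for COM, 23 for SPH and 1714 for TN, 44 for DB against COM, 122 for SPH against COM, 2026 for TK against COM, 920 for TN against COM, 49 for SPH against DB, 2242 for TK against DB, 1937 for TN against DB, 730 for TK against SPH and 248 for TN against SPH. Effective lengths as offsets gave 293 for COM, 454 for DB, 411 for TN, 3 for DB against COM, 18 for TN against COM, 1 for SPH against DB, 265 for TN against DB, 1336 for TK against SPH and 7 for TN against SPH. A term for serial numbers 1 to 14 against 15 to 27 gave 469 for DB, 373 for TN, 4 for SPH against DB, 18 for TN against SPH and 4 for TN against TK.

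DESeq2 called 817 genes for COM, 1404 for DB, 10 for DB against COM, 31 for SPH against COM, 327 for TN against COM, 12 for SPH against DB, 869 for TN against DB, 64 for TN against SPH and 444 for TN against TK. Voom with quality weights called 2391 for COM, 4697 for DB, 15 for SPH, 4009 for TK and 1309 for TN, 25 for DB against COM, 28 for SPH against COM, 5724 for TK against COM, 354 for TN against COM, 48 for SPH against DB, 7080 for TK against DB, 1512 for TN against DB, 3730 for TK against SPH, 33 for TN against SPH, 948 for TN against TK and 7613 between any groups. No low-count filter gave 9 for DB against COM, 246 for TN against COM, 3 for SPH against DB, 96 for TN against SPH and 375 for TN against TK.

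Fits on only the groups compared called 234 genes for COM, 261 for DB, 1 for SPH, 99 for TN, 2 for SPH against COM, 863 for TN against TK and 0 for DB against COM and for TN against COM, DB and SPH. Controls A and B alone gave 53 for COM, 26 for DB, 1 for SPH and 96 for TN, and controls C to G gave 1884 for DB, 2 for SPH and 1437 for TK. A fold of at least 2 left 46 genes for COM, 64 for DB, 1 for SPH, 277 for TK and 85 for TN, 3 for DB against COM, 6 for SPH against COM, 491 for TK against COM, 17 for TN against COM, 608 for TK against DB, 61 for TN against DB, 260 for TK against SPH, 2 for TN against SPH, 14 for TN against TK, 171 for bipyramids and 566 between any groups, where the furthest 2 group estimates were compared.

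The replicate letter as a replicate block called 409 genes for DB, 2 for SPH, 396 for TN and 834 for TN against TK. Libraries of the same letter in different groups correlated at -0.158 to 0.446 (median 0.068, 27 of 60 pairs over 0.1) against -0.468 to 0.363 for other letters (median -0.021, 46 of 240), and 14 of 27 libraries were closest to one of their own letter. The letters of COM, DB, SPH and TN follow the library sets. Within a set the median was 0.171 for the same letter (27 of 42 over 0.1) and 0.102 for other letters (31 of 62). As not every pair is over 0.1, the letters were not taken as pairs, though some sharing beyond the set is not ruled out.

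An estimated inter-gene correlation called 2 lists for COM, 3 for DB, 1 for SPH, 0 for TK and 1 for TN, or 3, 3, 1, 0 and 2 with the set term, and fry called 11 for COM, 2 for SPH and 5 for TN. With the controls split, overlaps were 50 genes for COM and DB, 34 for COM and TN, 19 for COM and TK, 17 for DB and TN, 13 for DB and TK, 130 for TK and TN, 1 for DB and SPH and 0 for SPH with COM, TK or TN.

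Leaving out 1 library at a time gave 127 (without COM B) to 826 (without COM C) genes for COM, 214 (without DB A) to 1863 (without DB C) for DB, 1 to 4 for SPH, 1472 (without TK C) to 2725 for TK, 133 (without TN A) to 1220 (without TN D) for TN and 2385 to 4137 between any groups. The ranges between forms were 1 (without COM B or DB A) to 9 for DB against COM, 1 (without COM B) to 17 for SPH against COM, 2415 (without COM A) to 4203 for TK against COM, 1 (without COM A) to 461 (without TN D) for TN against COM, 0 to 19 (without DB C) for SPH against DB, 3069 to 4890 for TK against DB, 89 (without TN A) to 942 (without DB C) for TN against DB, 843 (without SPH A) to 2321 for TK against SPH, 2 (without SPH C) to 134 (without TN D) for TN against SPH, 0 (without TK B or TK D) to 188 (without TN C) for TN against TK and 2491 to 3970 for bipyramids. Lists called ranged from 16 to 18 for COM, 18 to 21 for DB, 12 to 19 for SPH, 14 to 17 for TK and 8 to 14 (without TN B) for TN.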

Other observations

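The comparison of control libraries between sets, and the comparison of responses between sets, were chosen after the data were seen, as were the fits with the set term and so the counts over their splits. The counts over splits of the pooled fits were fixed before.

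Untreated cells of set 2 had lower levels of several gene groups than those of set 1. Of 18 matrix protease genes 13 were lower and none higher (camera adjusted p = 5e-15), of 21 immediate early genes 8 were lower (adjusted p = 0.0011), of 21 cholesterol synthesis genes 7 (adjusted p = 4.6e-07) and of 18 TGF-beta targets 7 (adjusted p = 1.1e-07). In the unfolded protein and ATF4 list 10 of 22 genes were higher and 2 lower (adjusted p = 1.2e-12). PSCA, a surface antigen, was lower by log2 3.08 (SE 0.17), TCN1 by 2.39 (SE 0.11) and SPRR2D by 1.41 (SE 0.17). Of 13 mitochondrially encoded transcripts 12 were lower (adjusted p = 3.5e-19). Mean fragment lengths were 257.9 to 319.1 nt in set 1, 197.6 to 297 nt in set 2 and 215.4 to 247.7 nt in set 3, and mitochondrial transcripts took 4.76 to 7.02%, 2.56 to 5.21% and 4.17 to 5.77% of counts. The response of cholesterol synthesis genes to COM, DB, SPH and TN was lower in set 1 than in set 2 by a median log2 of 0.31 (camera adjusted p = 3.4e-22, and unadjusted p = 0.00082 with estimated correlation).

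Counts of called genes were compared with other splits of the same libraries, of which the real one is included in the number as large. Chance can be excluded for COM against controls (543 genes, 2 of 100 splits as large), though controls C to F against the other libraries gave 1536, a split that follows set 2. The set term gave 1029 for COM against at most 182 (1 of 60), and within sets 661, 81 and 16. For DB (915 genes, 3 of 100) the highest other was 2750, with Control B, DB A, DB B and DB D on one side, all outside set 2. DB with the set term gave 1620 against at most 110 (1 of 60), and within sets 339, 85 and 368. For SPH (7 genes, 3 of 100) the highest other was 1282, with Control A, Control B, SPH A and SPH B, which are set 1, on one side. SPH with the set term gave 18 against at most 1 (1 of 60), and within sets 10, 9 and 1. The counts within sets do not bear on chance, since set 3 has 1 library a side and set 2 has 1 of each of these forms. Chance can also be excluded for TK (2569 against at most 4, 1 of 100, and 2487 against 66 with the set term, 1 of 70) and for TN (695 against 484, 1 of 100, and 1896 against 1768 with the set term, 1 of 60).

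Between forms, over splits that exchange libraries between the sets, chance can be excluded only for a grouping made without regard to the sets, for DB against COM (5 against 0, 1 of 35), SPH against COM (12 against 1, 1 of 35), TK against COM (3674 against 0, 1 of 35), TK against DB (4263 against 1, 1 of 35), TK against SPH (2034 against 0, 1 of 35), TN against TK (41 against 0, 1 of 35), bipyramids (3422 against 536, 1 of 100) and any groups (3468 against 197, 1 of 100). SPH against DB had 0 calls, so its splits (at most 4 calls, 35 of 35 as large) decide nothing. Chance cannot be excluded over the same splits for TN against COM (109 against 800, 2 of 35), TN against DB (543 against 603, 2 of 35) and TN against SPH (11 against 139, 3 of 35). The higher splits of these put COM A, B and D with TN D, DB A, B and D with TN D, and SPH A with TN A, B and C. Exchanged within the sets there are 12 splits of COM, DB, SPH or TN, too few for a share under 0.05, and TK lies in set 2 alone. With the set term these gave 32 genes against at most 1 for DB against COM (1 of 12), 88 against 0 for SPH against COM (1 of 12), 814 against 114 for TN against COM (1 of 12), 40 against 6 for SPH against DB (1 of 12), 1671 against 1731 for TN against DB (2 of 12) and 206 against 137 for TN against SPH (1 of 12). In the 1731 split, TN C changed places with DB C.

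Gene lists were called in most splits as well, at a median of 9 to 10 of 34 lists in the pooled fits, so camera at the preset correlation calls many lists without the real grouping. Pooled splits exchange libraries between sets and so decide nothing on the number called. Of 100 splits 4 were as large for SPH (17 against 19, from controls C to F of set 2). COM had 6 (18 against 20), DB 8 (19 against 23), TK 6 (15 against 16) and TN 68 (9 against 20). Within sets, with the set term, chance cannot be excluded for SPH (16 against 16, 3 of 60), COM (16 against 20, 8 of 60), DB (19 against 20, 4 of 60) and TN (11 against 15, 15 of 60), nor clearly for TK (16 against 16, 3 of 70).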
